A study of Mus musculus with 6 samples.

How the data were processed

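The series held 6 arrays made from 3 RNA pools of mouse lumbar spinal cord. Each pool was total RNA from 3 cords, taken from segments L3 to L5 at postnatal day 27, and each was hybridised once to each of 2 array types, called A and B here, as separate labelled extracts. Per the labels, 2 pools came from Egr3-deficient mice and 1 from wild-type mice. Pool 1 (RNA 450) and pool 2 (RNA 500) are the replicates labelled Egr3-deficient, and the wild-type pool is RNA 499. The labels of pool 2 and the wild-type pool carry a remark on acclimatization, missing for pool 1, and the number of pool 1 lies apart from the other 2, so pool 1 may belong to another batch. Pools were treated as the replicates, so every comparison set 2 pools against 1. The labels state no pairing between the groups.

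The authors deposited 1 linear intensity per probe set and array. The values were found to be scaled so that the mean left after trimming 2% from each tail was close to 150.0 on every array, from 149.965 to 149.98. The program that summarised probes into probe sets and its version are not given in the sources used here, and detection calls were not used here. Array type A held 22690 probe sets and array type B 22575, of which 64 on each were control probe sets and were left out of the tests. Of the others, 20380 on A and 14661 on B had 1 gene symbol, 691 and 245 had several, and 1555 and 7605 had none in the platform annotation used. Symbols were updated through the gene identifier where the RefSeq gene table of assembly GRCm38.p6 held it, for 20364 probe sets on A and 14499 on B. That table also gave gene neighbours and genomic gene lengths. Probe sets with several symbols were not named.

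Each array type was analysed alone. Values were transformed as log2(intensity + 16), quantile normalized across the 3 arrays, and kept where the mean log2 value reached the 40th percentile of the array type, which left 13576 probe sets on A and 13507 on B. Differences are on this log2(intensity + 16) scale and understate changes of dim genes. The fit used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment within the array type and an adjusted p threshold of 0.05. With 1 residual degree of freedom, the spread came from the 2 pools labelled Egr3-deficient and from the prior across probe sets. The lone wild-type pool was assumed to vary like them. The prior had 6.54 degrees of freedom on A and 52.3 on B. Adjusted p values rest on these pools only. The prior outweighs a probe set's own spread between the 2 pools, by far on B, so SEs and adjusted p values there hardly measure that spread.

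Beside the test, probe sets at least 2-fold apart from wild type in the same direction in both pools were counted. Because both ratios share the wild-type pool, unchanged data with the same spread were simulated for comparison. The simulation assumed that the wild-type pool varies like the other 2, so an excess over it cannot be tied to the genotype label. The fixed gene lists numbered 23 with 260 distinct genes, of which 234 were on either array type. A list used the probe set with the highest mean for each gene and was tested with at least 3 genes by camera with a preset correlation of 0.01, adjusted over the lists of the array type. Camera with an estimated correlation (statmod 1.5.0), fry and the percentile of the median among 10000 random lists matched on mean expression stood beside it. With 1 residual degree of freedom the estimated correlation itself rests on the difference between 2 pools. A further 4 lists (skeletal muscle, liver, choroid plexus and nuclear-retained noncoding RNAs) were written after the values were seen.

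Named genes followed a rule set before the data were examined. It took Egr3, members of the fixed lists as examples (those past the threshold first, then those with the largest smaller-of-2 ratio), and the 8 higher and 8 lower probe sets on A and 4 and 4 on B with the largest smaller-of-2 ratio, among those past the threshold and filled from all kept probe sets where fewer passed. Other genes named are said to have been chosen after their values were seen. On simulated data with 200 changed probe sets, the test recovered 8% of log2 changes of 1, 66% of those of 2 and 100% of those of 4 on A, and 4%, 58% and 92% on B. The number of arrays limits the precision. Alternatives were no quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, eBayes without trend, robust eBayes, adjustment over both array types, each Egr3-deficient replicate left out, the mean of all probe sets of a gene, and the other list tests. Scaling on the 100 probe sets present on both array types, and leaving out the muscle and liver list genes, were added after seeing the data.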

Results

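The series profiled gene expression in lumbar spinal cord of Egr3-deficient and wild-type mice, and its title places fusimotor neurons, the gamma motor neurons that innervate muscle spindles, at its centre. Egr3 is an immediate early transcription factor, and mice without it are known to lack muscle spindles and gamma motor neurons. The data were 2 RNA pools labelled Egr3-deficient (pool 1 and pool 2) and 1 wild-type pool, each of 3 cords and each measured on 2 array types. The median deposited intensity was 50.3, 57.9 and 60.1 on array type A and 76.2, 83.8 and 91.8 on array type B, in pool 1, pool 2 and wild type. The wild-type pool has no replicate, so its own spread is not measured.

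Egr3 itself was not lower in both pools labelled Egr3-deficient on either array type. On array type A its probe set read 24.9 and 52.7 in pools 1 and 2 and 40.6 in wild type, a log2 difference of 0.013 with an SE of 0.38 (limma adjusted p = 0.986), and the sign turned to -0.094 without quantile normalization. On array type B it read 210 and 107 against 75.3, a log2 difference of 1.03 with an SE of 0.51 (adjusted p = 0.348). The readings on A lay around the filter intensity of 36.7, so they decide little. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside the deleted part does not check the labels. The pools are therefore called by their labels throughout, and each direction drawn below rests on those labels.

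Skeletal muscle genes stood out on array type A, where they rose in both pools labelled Egr3-deficient. All 11 measured members of the skeletal muscle list were above wild type in both pools, 7 passed the threshold, 10 passed when adjusted over the list alone, and the median log2 difference was 3.62. Mylpf, a fast-fibre myosin light chain, read 594 and 608 against 8.41 (log2 difference 4.67, SE 0.31, adjusted p = 0.00479). Acta1, skeletal muscle actin, read 1096 and 1205 against 39.7 (4.42, SE 0.30, adjusted p = 0.00479). Ckm, muscle creatine kinase, read 519 and 563 against 34.9 (3.51, SE 0.31, adjusted p = 0.0104). Myl1, the troponin genes Tnni2 and Tnnc2, and the myosin heavy chain gene Myh1 rose by log2 differences of 4.74, 4.12, 4.20 and 3.92. Actn3, a fast-fibre actinin outside the list, was the 8th by rank at 3.05 and did not pass (adjusted p = 0.0516). Other muscle genes were above wild type on array type B. Mybpc2, of the further muscle list written after the values were seen, read 285 and 386 against 64.2. Myom2, a sarcomere protein gene outside both lists, read 153 and 219 against 6.06. Of the list itself 2 members were measured on array type B, and neither passed. There Ckm read 168 and 160 against 137 (log2 difference 0.35, adjusted p = 0.814), and Myh4, a fast myosin heavy chain gene, differed by 0.12 in pool 1 and 1.49 in pool 2 (adjusted p = 0.616).

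These 7 genes made up every call on array type A, with 9 probe sets higher and 0 lower by limma. At an unadjusted p under 0.05 there were 1077 higher and 1730 lower. The camera test gave the muscle list an adjusted p of 1.2e-14, and the adjusted p was 0.934 with an estimated correlation and 0.199 by fry. The same pools also differed in liver genes, chosen after their values were seen: Alb, the serum albumin gene, read 56.4 in pool 1, 3712 in pool 2 and 37.7 in wild type. Of the 11 muscle list genes, 1 reached the filter intensity of 36.7 in wild type. The count on A depended on the processing, with 227 higher and 597 lower under median centring, against 0 higher with no filter and 0 on scaling by shared probe sets, a setting added after seeing the data.

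**Figure D1:**
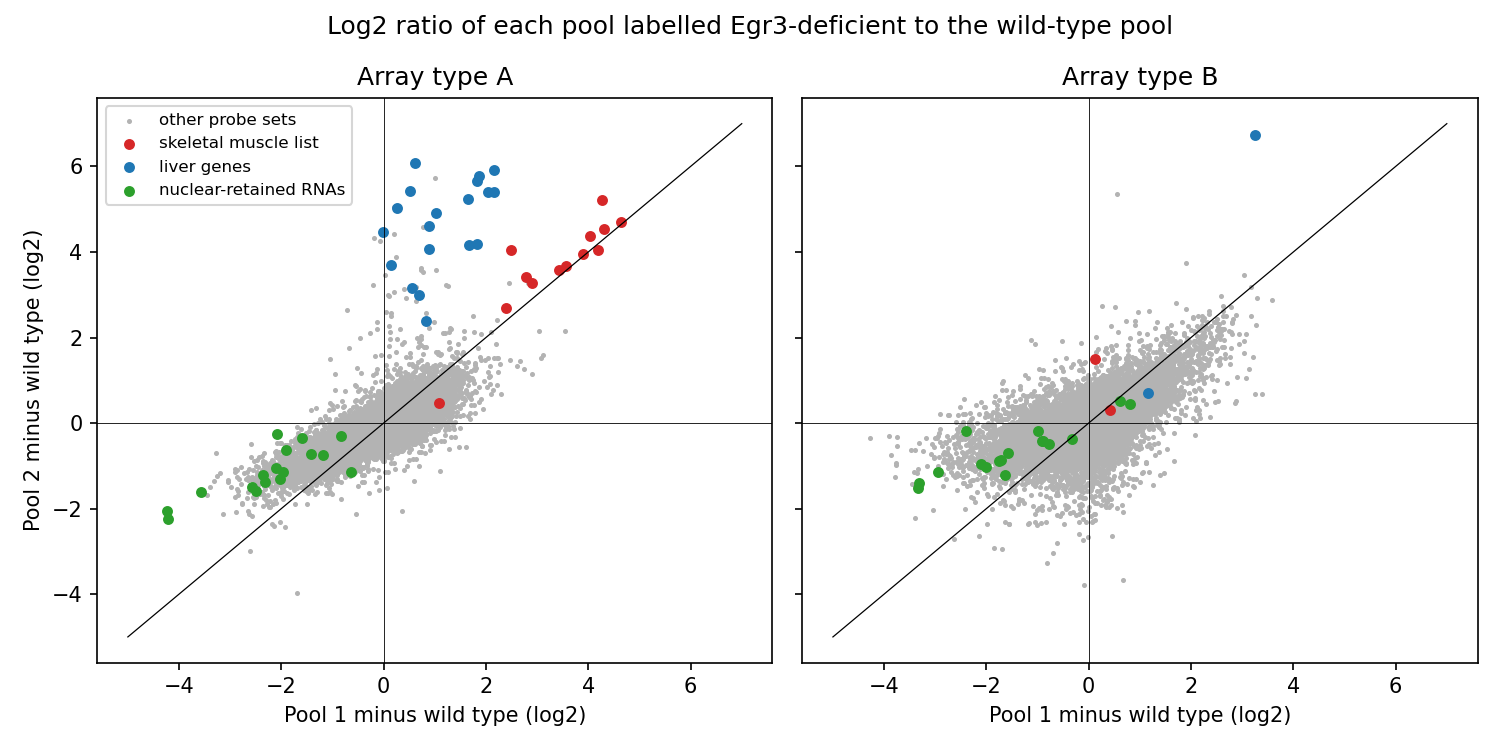
Log2 ratio of pool 1 (horizontal axis) and pool 2 (vertical axis) to the wild-type pool for every kept probe set on each array type, with the line of equal ratios. On array type A the skeletal muscle list lies high in both pools (median 3.62), liver genes lie high mainly in pool 2, and nuclear-retained RNAs lie low; the coloured liver and nuclear genes were chosen after their values were seen.

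Many probe sets were lower in both pools labelled Egr3-deficient on array type A, but none of them passed the test. Gmfb, glia maturation factor beta, read 60.2 and 48.2 against 483 (log2 difference -2.81, SE 0.34, adjusted p = 0.060). Malat1, a nuclear long noncoding RNA, had a difference of -3.23, with -4.21 in pool 1 and -2.24 in pool 2. The translation initiation factor gene Eif3a (-2.28), 6820431F20Rik (-2.38), the cyclin-dependent kinase gene Cdk14 (-2.28), Tmem47 (-2.38), the dynein light chain gene Dynlt3 (-2.63) and the chloride cotransporter gene Slc12a2 (-2.48) were next by the same rule and did not pass either. In all, 590 probe sets were at least 2-fold lower in both pools and 163 were at least 2-fold higher, where unchanged simulated data gave 57 and 62. With pool 1 set against the other 2 pools, 250 were lower in it and 89 higher. An excess over the simulated counts is thus not particular to the labels. In pool 1 alone 1647 were lower and 707 higher, and in pool 2 alone 686 and 333, so pool 2 set the limit. In the same pools the 3' to 5' signal ratio of the 18S ribosomal RNA control on A was 2.27 and 1.08 against 0.0493 in wild type. Gmfb passed under median centring and without quantile normalization. Meg3, another nuclear noncoding RNA, chosen after its values were seen, read 450 and 943 against 1826.

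On array type B, genes of several kinds differed between the pools labelled Egr3-deficient and wild type. Ttr, the thyroid hormone carrier transthyretin, was the highest by rule at a log2 difference of 4.99 (SE 0.59, adjusted p = 2.2e-07), but read 584 in pool 1 and 6739 in pool 2 against 50.9. Csrnp1, a nuclear protein gene, rose by 3.17 (adjusted p = 0.00269), Myom2, a sarcomere protein gene, by 3.24 and the phosphatase subunit gene Ppp1r16a by 3.10. Rgs7bp, which anchors a regulator of G protein signalling, fell by 2.54 (SE 0.46, adjusted p = 0.00126). Fam126b fell by 2.00, Pex5l, a regulator of ion channel trafficking, fell by 2.02, and Kank1, a cytoskeletal regulator gene, fell by 1.80. Ttr lost its call with robust eBayes, and Kank1 under median centring. The SD between the 2 pools was 2.46 for Ttr, so its SE of 0.59 came mostly from the prior across probe sets. Limma called 138 probe sets higher and 82 lower, and the 2-fold counts were 577 higher and 243 lower against 224 and 217 in unchanged simulated data. The calls were 119 and 22 under median centring, 2 and 0 without quantile normalization, and 0 and 0 without the intensity trend, with no filter or on shared scaling; at an unadjusted p under 0.05 there were 1000 higher and 923 lower. The 2-fold counts were 680 and 134 under median centring. With pool 1 set against the other 2 pools, 199 were at least 2-fold higher in it and 748 lower. The excess over the simulated counts is thus not particular to the labels. Pool 1 alone gave 1420 higher and 1710 lower, and pool 2 alone 790 and 655. Scaled on the shared probe sets, as chosen after seeing the data, the 2-fold counts were 143 and 1781, because that scaling moved the median of all probe sets to -0.67.

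The fusimotor markers had no call as a list on either array type. For scale, kept genes outside the 10 Mb around Egr3 had a median log2 difference of 0.17 on A and 0.11 on B. The camera test compares a list with the other genes, so it can point down beside a positive median. On simulated data the test recovered 8% of log2 changes of 1 on A and 4% on B. The RNA came from cord segments, and the share of gamma motor neurons in it was not measured. A loss of these cells could therefore be missed. Before the filter, 4 of 9 members were above wild type in both pools and 3 below on A, and 4 of 12 above and 5 below on B. On array type A 3 of 5 measured members were above wild type in both pools and 2 below, none passed, and the median was 0.37 (camera adjusted p = 0.872). On array type B 3 of 10 were above and 4 below in both pools, none passed, and the median was -0.073 (adjusted p = 0.667). Its sign turned to 0.16 under median centring on B, and with the filter at the 60th percentile it was -0.098 on A and 0.023 on B. On shared scaling it was -0.59 on B, where the median of all probe sets was -0.67. The nuclear receptor gene Esrrg, a gamma motor neuron marker, differed by 0.38 on A and -0.70 on B, and Gfra1, a receptor for glial cell line derived neurotrophic factor, by -0.43 on A and -0.12 on B, where its sign turned without quantile normalization and under median centring. Wnt7a differed by 0.54 on A and 0.077 on B, where pool 1 was at 0.69 and pool 2 at -0.54. Stxbp6 differed by -0.098 on A and -1.17 on B (adjusted p = 0.132).

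Other motor neuron and neuronal lists had no call as lists. The alpha motor neuron markers had medians of 0.31 on A and -0.18 on B, the motor neuron and cholinergic genes 0.036 and 0.17, and the pan-neuronal genes -0.14 and -0.53, with no member past the threshold. The sign on B turned for the alpha motor neuron and pan-neuronal lists under median centring, that of the alpha list also without quantile normalization, and that of the cholinergic list on A without it. Chodl, an alpha motor neuron marker, read 85.3 and 174 against 299 and did not pass. Map2, a dendritic microtubule protein gene, differed by -1.68 on A, and on B by -1.36 in pool 1 and -0.64 in pool 2. Adjusted over the list alone, 4 pan-neuronal genes were lower on A and 2 on B. Inhibitory interneuron genes had medians of 0.043 and 0.088, with a test pointing down on A. Excitatory interneuron and dorsal horn genes had a median of 0.53 on A, where Cck, a neuropeptide gene, passed adjusted over the list alone. Neurotrophic factors and receptors had medians of 0.21 and 0.0070, and their means and tests were below 0 on both. Lifr, a cytokine receptor gene, was lower on A adjusted over the list alone (log2 difference -1.84). Proprioceptive afferent genes had a median of -0.17 on B, which turned positive under median centring. On shared scaling the inhibitory, cholinergic and neurotrophic medians on B were negative.

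The EGR family, cofactors and immediate early genes tended to be above wild type on array type A. Of 15 measured members 12 were above it in both pools, 0 passed over all probe sets and 2 passed adjusted over the list alone. The median was 0.43 and the camera adjusted p 0.0468, which was 0.934 with an estimated correlation and 0.150 by fry. It was also above the threshold without quantile normalization (0.0555), under median centring (0.0580), at a pseudocount of 64 and at the 60th percentile filter. Over all settings it ran from 0.0155 to 0.934. Fos, an AP-1 transcription factor gene, had a log2 difference of 1.59 (SE 0.33, adjusted p = 0.161), and Egr1, of the same family as Egr3, read 284 and 432 against 134 (1.36, adjusted p = 0.161). Hspa1b, an inducible chaperone gene, read 426 and 137 against 37.1 in the same pools. Fosl2 differed by 1.11 on A and by 1.48 on B. On B the list had 3 genes and a median of 0.22, which was negative on shared scaling; adjusted over the list alone Fosl2 was higher and Homer1 (-1.12) lower.

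Glial and vascular lists had no call as lists, though single members on array type B did. The astrocyte list had medians of 0.035 on A and -0.69 on B. Its mean and test pointed down on A, as did the median without quantile normalization. Aqp4, the astrocyte water channel gene, fell by 1.84 on B (adjusted p = 0.0115) and differed by -1.74 on A (adjusted p = 0.158). Slc1a2, a glutamate transporter gene, fell by 1.18 on B, with -1.88 in pool 1 and -0.48 in pool 2, where the deposited value of 7489 was not below the 7384 of wild type. Its probe set on A differed by 0.050 (adjusted p = 0.944). Ermn, a myelin protein gene, fell by 1.72 on B (adjusted p = 0.00988), while the oligodendrocyte and myelin lists had medians of -0.20 and 0.069, the latter with a test pointing down. Adjusted over the list alone on A, the astrocyte gene Aqp4 and the myelin list genes Ugt8a (-1.37) and Aspa (-1.24) were lower. Aqp4, Slc1a2 and Ermn on B no longer passed under median centring, without quantile normalization, with no filter or without trend. Oligodendrocyte precursor markers had medians of 0.099, with a test pointing down, and 0.66, and adjusted over the list alone on A Sox10 (0.97) and Olig2 (1.17) were higher and Vcan (-1.21, but 0.87 on B) lower. On A the microglia list had a median of 0.31, endothelial markers 0.20, meningeal and fibroblast genes 0.22, Schwann cell and nerve root genes 0.23, axon injury genes 0.37, and stress and heat shock genes 0.61, with 3 genes higher and 1 lower adjusted over the list alone and 5 of 13 below wild type in both pools. The lower one, Hsp90aa1, a chaperone gene, had a log2 difference of -1.46 on A and 0.61 on B. Among the matched random lists on A, the stress list median lay at percentile 99.99. The excitatory interneuron and EGR lists lay at 96.4 and 96.3, and the pan-neuronal and myelin lists at 2.99 and 2.91. Genes are not independent replicates, so these percentiles do not measure the spread between pools. Lists with fewer than 3 measured genes on an array type were not tested there, which left out the dorsal root ganglion, ependymal, red blood cell and sex-linked lists on both. Unfiltered and in pools 1 and 2, dorsal root ganglion genes had medians of -0.52 and -0.88 on A and 0.34 and -0.36 on B, ependymal genes 0.61 and 0.53 on A and 0.59 and 0.46 on B, and sex-linked genes -0.64 and -0.44 on A and -2.35 and -1.93 on B. Red blood cell genes, measured on A, had medians of 1.32 and -0.048. Adjusted over the list alone, the ependymal genes Rarres2 (1.22) and Mia (0.90) and the red blood cell gene Alas2 (1.97) were higher on A and the Schwann cell gene Pmp2 (-0.88) was lower on B. Each of these lists had only 2 kept genes on that array type, so this adjustment differs little from none. These genes did not pass over all probe sets.

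**Figure D2:**
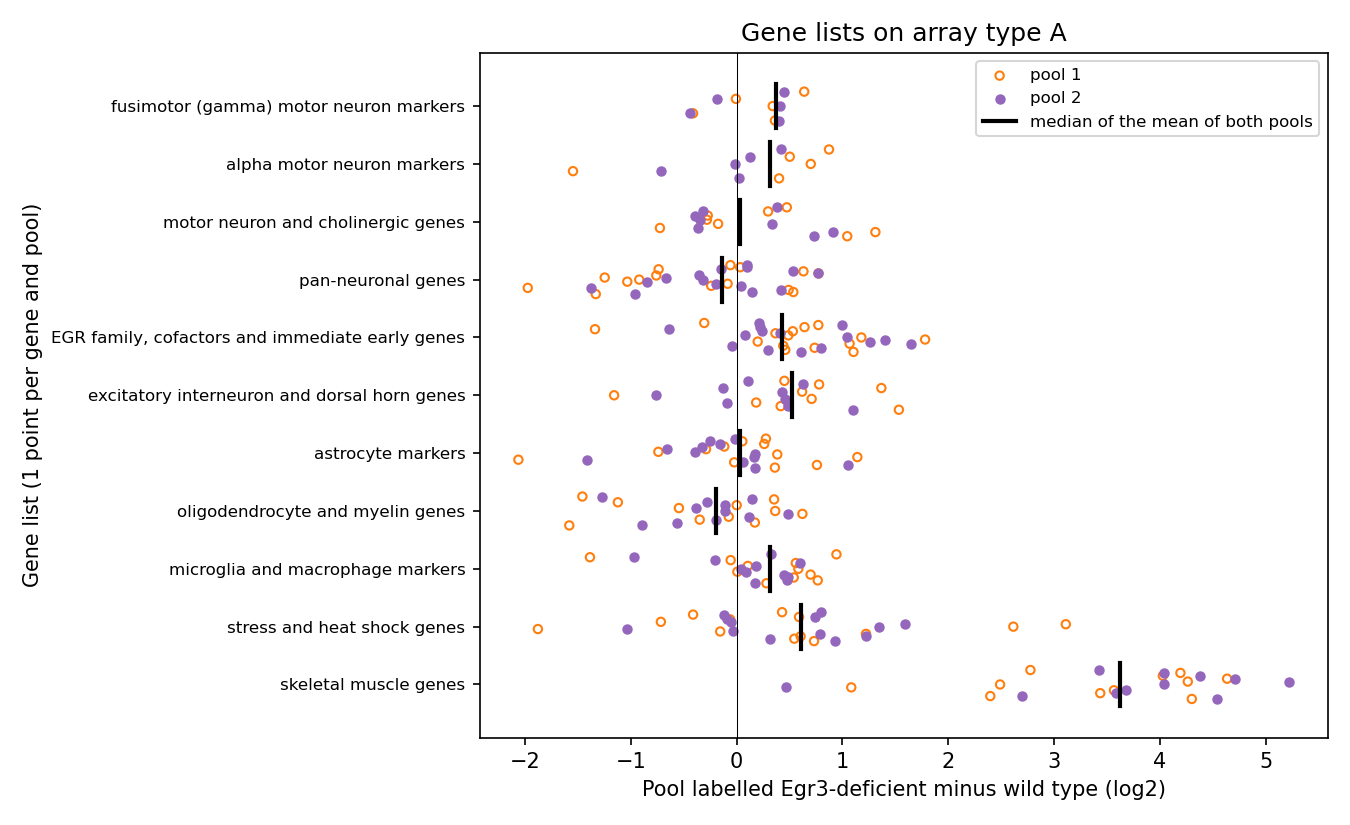
Log2 difference from wild type on array type A for each measured gene of 11 lists, in pool 1 (open circles) and pool 2 (filled circles); bars mark the median over genes of the mean of both pools. The skeletal muscle list stands apart at a median of 3.62, while the fusimotor list has a median of 0.37.

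The 2 pools labelled Egr3-deficient also differed from each other. The SD across probe sets of the log2 difference was 0.787 for pool 1 and 0.617 for pool 2 against wild type and 0.490 between the 2 pools on A, and 0.889, 0.657 and 0.676 on B. The ratios of the 2 pools to wild type correlated across probe sets at 0.78 on A and 0.65 on B, where unchanged simulated data gave 0.50 and 0.51 from the shared wild-type pool alone. Their covariance was 0.380 against a simulated 0.103 on A, and 0.382 against 0.202 on B. Probe sets are not independent replicates, and part of the excess may come from the shared wild-type pool. The ratio of 3' to 5' signal of the Gapdh control was 0.858, 0.975 and 0.734 on A in pool 1, pool 2 and wild type, and 0.923, 0.805 and 0.755 on B. That of the actin control was 1.37, 1.48 and 1.36 on A and 1.40, 1.47 and 1.52 on B. The ratio was lowest in wild type on both array types for Gapdh, for 18S ribosomal RNA (1.43, 0.945 and 0.0605 on B) and for pyruvate carboxylase (4.20, 3.80 and 2.42 on A and 5.82, 4.02 and 3.85 on B). It was 1.55, 2.29 and 1.56 on A and 2.57, 2.54 and 2.11 on B for the transferrin receptor. On A the 5' transferrin receptor probe set read 11.6 and 12.6 in pools 1 and 2, below the filter intensity of 36.7. The 5' pyruvate carboxylase probe set read 41.4, 43.7 and 47.3 on A, near that intensity, so these 2 ratios are uncertain there.

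The 2 array types gave related differences. The 100 shared probe sets had a Pearson correlation of 0.874 and a median absolute difference of 0.288, but their median difference from wild type was 0.12 on A and 0.45 on B, and 0.12 and 0.73 without quantile normalization. The same probe sets were thus further above wild type on B. Across 2005 genes measured by other probe sets the correlation was 0.526, and 68.9% had the same sign. Of these genes 92 were at least 2-fold lower on both array types, 7 at least 2-fold higher and 3 opposite. Both array types measured the same 3 pools, so this is technical repeatability and adds no replicate.

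Genes near Egr3 on chromosome 14 were compared with genes elsewhere, because a knockout can carry flanking DNA of another strain. On array type A the 72 genes within 10 Mb had a median 0.23 log2 units below the rest (difference -0.23, two-sided permutation p = 0.0031, adjusted over both array types 0.0062), and on B the 65 genes differed by -0.15 (p = 0.153). Genes are not independent replicates. With the trend with gene length removed, a step added after seeing the data, the difference was -0.030 on A (two-sided permutation p = 0.695) and -0.18 on B (permutation p = 0.0656).

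**Figure D3:**
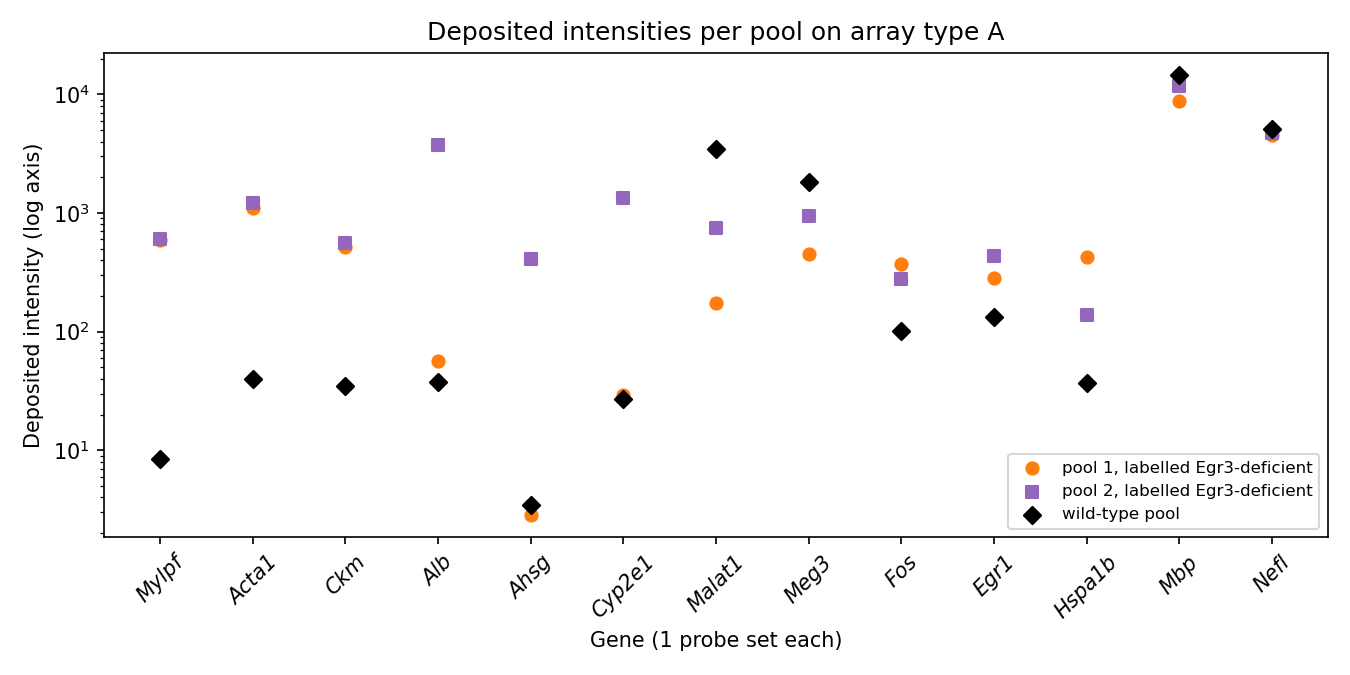
Deposited intensity on a log axis of 13 genes on array type A in the 3 pools, 1 probe set per gene; several of the genes were chosen after their values were seen. Acta1 reads 1096 and 1205 in pools 1 and 2 against 39.7 in wild type, and Alb reads 3712 in pool 2 alone.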

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

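The rule for control probe sets was chosen after their values were seen. They lay outside the tests, and 2 of 64 on array type B were at least 2-fold above wild type in both pools labelled Egr3-deficient, with none on array type A. Both target the bacterial lys transcript, a labelling control. Their smaller log2 ratios were 1.03 for the 3' probe set, which read 511 and 596 against 241, and 1.01 for the middle one, which read 145 and 181 in the 2 pools. In the other direction, 4 of 64 controls on each array type were at least 2-fold below wild type in both pools. They were the 5' probe set of 18S ribosomal RNA, which read 43.7 and 136 against 3068 on A and 238 and 521 against 8125 on B, and the 3 transferrin receptor probe sets, at log2 ratios from -1.67 to -1.27 on A and from -1.92 to -1.28 on B. All these control ratios were taken without quantile normalization. Without it, the median difference of the 100 shared probe sets from wild type was 0.12 on A and 0.73 on B. The smaller lys ratios on B were not corrected for that shift, so they show no 2-fold rise beyond it. The bacterial dap, phe and thr controls were also above wild type in pool 2 on both array types. On B they lay closer to wild type in pool 1: the middle DapX probe set read 1319 and 2718 in pools 1 and 2 against 1256. No test was run on any of these control probe sets. No explanation was tested.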

How the results depend on the processing

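The scaling on shared probe sets and the omission of muscle and liver list genes were chosen after seeing the data. Counts were unstable, and the cause was not tested except where fewer or more probe sets entered or 1 pool was left out. Signs were followed for the named genes and the lists only, and none of those with a call changed sign. Calls on A (9 higher, 0 lower) were 227 and 597 under median centring, 0 higher with no filter, 0 higher on shared scaling, 0 higher without muscle and liver list genes, and 17 and 9 adjusted over both array types. Lower calls on A were 1 as deposited, 1 at a pseudocount of 64 and 1 with robust eBayes. Calls on B (138 higher, 82 lower) were 2 and 0 as deposited, 0 and 0 with no filter, 0 and 0 without trend, 0 and 0 on shared scaling, and 80 and 41 adjusted over both array types. Lower calls on B were 22 under median centring, 47 and 181 at pseudocounts of 1 and 64, 195 at the 60th percentile filter and 170 with robust eBayes. The 2-fold counts on A (163 and 590) were 339 higher at a pseudocount of 1, 45 and 233 at 64, 259 higher with no filter and 97 higher at the 60th percentile filter. Those on B (577 and 243) were 134 lower under median centring, 232 and 114 at a pseudocount of 64, 1007 and 800 with no filter, 311 and 147 at the 60th percentile filter, and 143 and 1781 on shared scaling. With 1 replicate left out, 1 pool alone had to pass, and the 2-fold counts were 333 to 707 higher and 686 to 1647 lower on A, and 790 to 1420 higher and 655 to 1710 lower on B. Calls were not counted there, since 1 array against 1 leaves no test. The Egr3 difference on A (0.013) was -0.094 as deposited and -0.093 on shared scaling, and -0.29 to 0.31 with 1 replicate left out; it has no value at the 60th percentile filter. On B it was 0.57 to 1.49 with 1 replicate left out. The fusimotor median was -0.098 on A and 0.023 on B at the 60th percentile filter, 0.16 on B under median centring, and -0.24 to -0.13 on B with 1 replicate left out. The median over all probe sets was 0.13 on A under median centring against 0.054, and on B it was -0.67 on shared scaling against 0.017. Among named genes and lists, 66 gene values and 9 list values lost a call and 40 gene values gained one. No paired analysis was possible, since there was 1 wild-type pool and the labels state no pairing between the groups. Dim probe sets limit the rest, since signal over background is not given.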

Other observations

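The lists of further muscle, liver, choroid plexus and nuclear-retained genes were written after their patterns were noticed. The tests of pool 1 alone, of a gradient, of other choices of the lone pool and of the length trend as a whole cause were chosen after their results were already in view.

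The nuclear-retained long noncoding RNAs were picked after their values were seen and were not tested as a group, and 590 probe sets of any kind were at least 2-fold lower in both pools on array type A. On that array type all 6 listed were below wild type in both pools, with medians of -2.10 in pool 1 and -0.89 in pool 2, and on B 7 of 8 were. Malat1 did not pass on A (limma adjusted p = 0.161). Meg3 read 450 and 943 against 1826 on A, and Neat1 was the exception on B. The sex-linked genes measured were also below wild type in both pools. Eif2s3y, on the Y chromosome, read 0.939 and 6.98 against 32.1 on A, and Uty 6.74 and 4.18 against 120 on B, with no test. None of the Y-linked genes of the list passed the filter. The X-linked Xist, also among the 6 nuclear-retained RNAs, read 121 and 193 against 244 on A. These genes were picked out after their values were seen. Alas2, a red blood cell gene, read 104 and 49.2 against 7.04 on A, but the other measured genes of its list did not follow: Slc4a1 read 144 and 39.6 against 54.9, and Hba-a1 had log2 ratios of -0.086 and -0.048. The 5' control for 18S ribosomal RNA read 43.7 and 136 against 3068 on A.

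Skeletal muscle genes were higher in both pools labelled Egr3-deficient. The pattern is defined by both pools, with a list median of 3.57 in pool 1 and 4.04 in pool 2, so setting it against a difference of pool 1 alone was no independent test. Muscle tissue carried with the cords was tested on 15 further muscle genes on array type A. Of these, 13 were above wild type in both pools and 2 below. The smaller of the 2 median log2 ratios was 0.796, between the bounds set for and against. These genes were dim, with median intensities of 53.7 and 58.9 in pools 1 and 2 against 29.0 in wild type. The log2 scale used here understates changes of dim genes, so this value cannot decide the question. On array type B, outside the test as set, all 6 were above wild type, with medians of 1.09 and 1.36. Carried tissue may therefore be a source and cannot be told apart from a difference that goes with the genotype label, which was not tested. Acta1 read 1096 and 1205 against 39.7, and 6 of the 15 further genes reached the filter intensity in wild type, which is no detection call.

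Liver genes were highest in pool 2. Choroid plexus also makes transthyretin, and its 8 other genes on A had a median log2 ratio of 0.176 in pool 2, past the bound set against it. Only 2 of the 8 passed the filter, so these dim genes cannot exclude a small amount of choroid plexus RNA. Ttr on B also read 584 in pool 1 against 50.9 in wild type. The further liver genes on A had a median of 0.294 in pool 1, so the source of Ttr there is not settled. Of 12 further liver genes 11 were at least 2-fold above wild type in pool 2 and none in pool 1, and their median was 3.92, consistent with liver RNA in pool 2. Alb read 3712 against 37.7 and Cyp2e1 1335 against 26.9, and 2 of the 12 reached the filter intensity in wild type. The 2 further liver genes on array type B, Apoh and Apob, went the other way, with medians of 1.54 in pool 1 and 0.40 in pool 2. Apoh read 275 and 198 against 125 there, but 55.8 and 365 against 34.3 on A, so its probe sets disagreed. Apob did not pass the filter on either array type. A genotype difference was not tested.

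The broad shift on both array types ran with gene length: the Spearman correlation across genes of the log2 difference with genomic length was -0.374 on A and -0.255 on B, and genes are not independent replicates. Removing that trend left 56.6% on A and 78.7% on B of the genes that were 2-fold apart in both pools, past the bound set against length as the whole cause. Only 139 of 271 lower genes on A stayed, and the count of higher genes there went from 107 to 148. Spread of single genes around the trend also keeps genes past a 2-fold cut. The bounds were set after the correlations were known, so this does not decide whether length is the whole cause. The difference between pools 1 and 2 correlated with the mean difference from wild type at 0.367 on A and 0.377 on B, which shows only that pool 1 lay further from wild type, and ran with gene length at -0.175 and -0.189, short of the bound of -0.2, so a gradient over all 3 pools cannot be told apart from a genotype difference. All 3 choices of the lone pool gave at least the 9 calls on A, up to 158 with pool 1 alone, which points to a structure of the samples whose cause was not tested, and 1 of 3 gave the 220 on B, where the highest other was 66. With 3 choices no share can fall under 0.05. By the 2-fold rule on A, 590 probe sets were higher and 163 lower in the lone wild-type pool. With pool 1 as the lone pool there were 89 and 250, and with pool 2 there were 88 and 15. On B the wild-type pool gave 243 and 577, pool 1 gave 199 and 748, and pool 2 gave 71 and 250. By that rule the wild-type pool was thus not ahead in both directions on B.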
